A study of Homo sapiens with 6 samples.

How the data were processed

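Gene expression was measured on 6 arrays of MO3.13 cells, 3 control and 3 Klotho-treated, and the groups were taken from the sample titles. Per the labels' protocols, total RNA was isolated with Trizol and a column, and biotinylated cDNA was prepared by NuGEN amplification from 100 ng of total RNA. The authors deposited 1 table of log2 values, with 1 value per probe set and array; the submitters' processing notes name RMA (background correction, quantile normalization and summarization), without a version. The software, the annotation and any filter of probe sets are not given in the sources used here. The array medians (6.36 to 6.47) differed slightly, so the summarized values were not exactly equal in distribution. The platform is an Affymetrix-type exon array summarized to whole transcript clusters, per the header of the probe annotation.

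No intensities, detection calls or control-probe marks were used, since only the log2 table was at hand. All 22011 probe sets were therefore tested, among them 5171 that the probe annotation leaves unnamed and that may include control probe sets, which the test plan meant to leave out. There were 14432 with 1 gene symbol and 2408 with several. Of those with 1 symbol, 14404 matched the RefSeq gene table of GRCh38.p14 by Entrez number, and no symbol needed updating. A gene was represented by the probe set paired with it alone that had the highest mean over the 6 arrays, which gave 14232 genes. No gene was named from a probe set with several symbols. A probe set with a single symbol can still hybridise to transcripts of near-identical copies.

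Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, 2-sided, 1 prior variance), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Intervals are 95% intervals from the moderated variance. A total of 38 gene lists were written before the data were examined, as were the test design, the rule for naming genes and all but 3 of the alternatives. Lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 38 lists, and again with camera's estimated correlation and with fry. Counts adjusted over a list alone use the same limma p-values and are not adjusted across the 38 lists. The named genes are, since no gene passed, the 5 in each direction with the smallest p whose 3 treated and 3 control values do not overlap (leaving out symbols of uncharacterised loci and small RNAs); up to 4 members per list with the smallest p, of which the text gives at least the first 2 where they are not already given; and a fixed set of Klotho-related, myelin and growth response genes, of which SOD2, ADAM10 and ADAM17 had no probe set of their own and another is not reported here.

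The fit was tested on simulated data: 10 sets of 22011 probe sets with the real means and with variances drawn from the prior fitted to the real ones, in which 50 genes were changed at each fold. It recovered 23.4% of 1.5-fold, 78.2% of 2-fold, 97.8% of 3-fold and 99.4% of 4-fold changes. All 25 lists planted with a shift of 0.3 on the log2 scale were recovered by each list test. The simulated arrays hold no component shared between probe sets, which the real arrays do.

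Array data give no read depth, and the number of arrays limits the precision. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical. No scan dates or slides were at hand to test as batches. Alternatives were other scalings between arrays, filters on dim probe sets, other variance models, array quality weights, the replicate number as a block, means of all probe sets of a gene, other list tests and leaving out each array in turn. A difference that was past neither the adjusted threshold nor an unadjusted p under 0.05 was not counted as reversed when its sign changed, and such sign changes were counted separately. Chromosome positions were not used here.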

Results

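Transcript levels were measured in MO3.13, a human cell line that the submitters describe as an oligodendroglioma line, with and without exposure to Klotho. Klotho is a membrane and circulating protein best known as the co-receptor through which the hormone FGF23 signals by way of FGF receptors, and the study's title names signalling pathways in this line as what Klotho was examined for. The treated cells had received recombinant mouse Klotho at 0.4 µg/mL in medium without serum for 3.5 h. The control cells were described only as grown in medium with 10% fetal bovine serum, so that the labels name serum-free medium for the treated group alone. Each group consisted of 3 arrays, and each array gave 22011 log2 values, 1 per probe set, with array medians between 6.36 and 6.47. The 6 arrays correlated with each other at r = 0.985 to 0.991 across probe sets. Pairs of arrays within a group (mean r = 0.989, 6 pairs) were no more alike than pairs between groups (mean r = 0.989, 9 pairs).

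The comparison of treated with control cells asked which transcripts differ after 3.5 h of Klotho. No probe set passed. Of the 22011 tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.343. At an unadjusted p under 0.05 there were 703, of which 292 were higher and 411 lower in the treated cells, against 1101 that chance alone would give. This count was above that of chance without treated array 3 (1200) and with array quality weights (1644), with 0 past the adjusted threshold in both. The split moved with the scaling of the arrays: it was 510 higher and 253 lower with each array centred on its median, 371 and 322 with quantile normalization, and 338 and 374 with cyclic loess. Among the 14232 genes with a probe set of their own, 295 had an unadjusted p under 0.05 against 712 by chance. These gene values use the variance prior fitted to all probe sets, the unnamed ones included. Fitted alone, the same genes gave 438, with 0 past the threshold and a smallest limma adjusted p of 0.151, against 0.395 in the fit of all. The treated and control values did not overlap for 7.89% of the genes, against the 10% that chance gives with 3 arrays per group.

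The arrays set close bounds on the size of any difference in signal for most genes. The standard error of a gene's log2 difference had a median of 0.11, with 0.08 and 0.17 at the 10th and 90th percentiles. The 95% interval of the difference lay within a 2-fold change in either direction for 14047 genes (98.7%) and within a 1.5-fold change for 13053 genes (91.7%). These intervals hold gene by gene and not for all genes at once. No detection calls were used, so the shares include dim probe sets, for which a bound on the signal need not bound the transcript. Simulated arrays, with variances drawn from the fitted prior, gave back 78.2% of planted 2-fold changes and 23.4% of planted 1.5-fold changes at the adjusted threshold. Their noise was independent between probe sets, whereas the real arrays share a component, so these shares need not hold for the real arrays. A 1.5-fold change of a single gene was mostly missed in the simulated arrays. The simulated sets also held planted 3-fold and 4-fold changes, which ease the adjusted threshold for the smaller ones. The 78.2% therefore does not give the chance of calling a 2-fold change without such a background. Of the 4 genes that differed by more than 2-fold here, 0 passed.

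The genes with the smallest p in each direction are given as values only, since none passed the threshold. NPM1, nucleophosmin, a nucleolar protein of ribosome assembly, measured 3.38 ± 0.21 in control and 2.33 ± 0.08 in treated cells (log2, SD, n = 3), a difference of -1.05 (95% interval -1.35 to -0.76) with an adjusted p of 0.395 in limma. This probe set is the only one paired with NPM1 alone, 2 others pair the gene with a second one, and NPM1 has near-identical pseudogene copies. The olfactory receptor gene OR52N2 differed by -0.82 (95% interval -1.15 to -0.49), the secreted matrix protein gene CCDC80 by -0.52, the zinc finger gene ZNF536 by -0.50 and the antisense transcript RUSC1-AS1 by -0.42. In the other direction were the histone gene H2BC10 (0.59), MC2R, the receptor for adrenocorticotropic hormone (0.59), PRM1, the sperm protein protamine 1 (0.57, 95% interval 0.38 to 0.76), the hair keratin-associated gene KRTAP3-1 (0.42) and the transcription factor gene PRDM12 (0.39). Of these 10 genes, 6 had probe sets below the lower quartile of mean signal, and OR52N2, PRDM12, ZNF536 and CCDC80 did not. The adjusted p was 0.554 for PRM1 and 0.998 for the other 8.

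**Figure D1:**
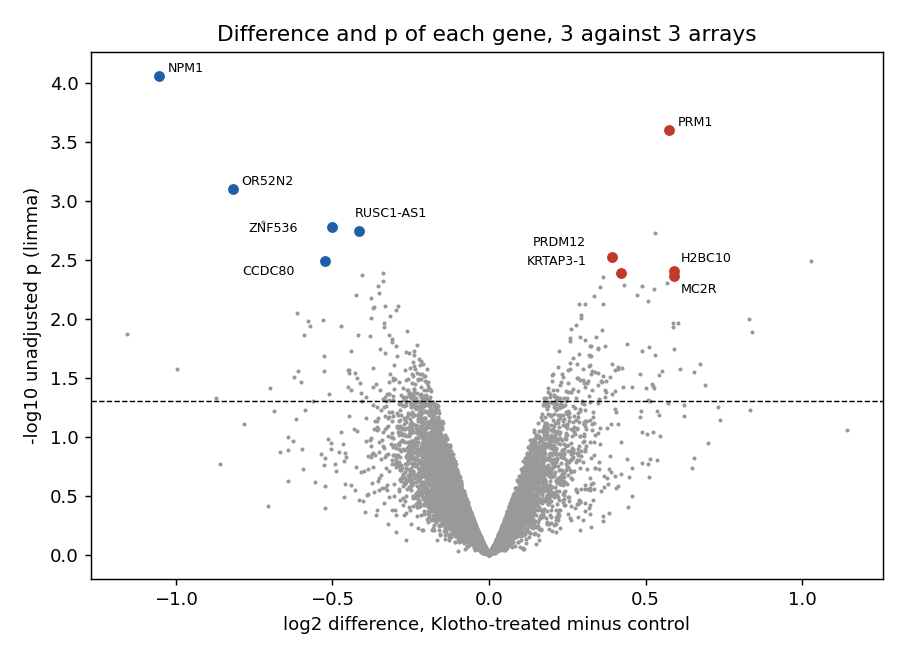
Points are genes with a probe set of their own, with the log2 difference (treated minus control) on the x axis and -log10 of limma's unadjusted p on the y axis, and the dashed line marks an unadjusted p of 0.05. The 10 named genes (red higher, blue lower in treated cells) have the smallest p among genes whose groups do not overlap, and none has an adjusted p under 0.05.

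No gene through which Klotho acts, or that Klotho is described as regulating, passed the adjusted threshold in limma. KL, which encodes human Klotho itself, measured 3.92 ± 0.18 in control and 3.97 ± 0.03 in treated cells (log2, SD, n = 3), and its relative KLB, the co-receptor for FGF19 and FGF21, 4.57 ± 0.17 and 4.73 ± 0.04. The KL probe set was dim, below the lower quartile of mean signal of all probe sets (4.70). FGFR1, the main receptor partner of Klotho, measured 7.33 ± 0.12 and 7.29 ± 0.12, with a 95% interval of the difference of -0.30 to 0.20. The differences of FGFR2, FGFR3 and FGFR4 were -0.06, -0.03 and -0.12, and the 95% intervals of all 4 receptors lay within a 1.5-fold change. Of 26 measured genes of the Klotho and FGF list, 0 passed the threshold over all probe sets and 0 passed when adjusted over the list alone; the adapter gene FRS3 (-0.27) and FGFRL1 (-0.17) came nearest, and camera gave the list an adjusted p of 0.875. Among 21 measured sheddases, channels and transporters tied to Klotho, 3 had an unadjusted p under 0.05 and groups that did not overlap, and 0 passed over all probe sets or adjusted over the list alone. These were the potassium channel gene KCNJ1 (-0.31, 95% interval -0.54 to -0.08), the vitamin D receptor gene VDR (0.36, 95% interval 0.04 to 0.69) and the calcium sensor gene STIM1 (-0.24, 95% interval -0.46 to -0.02), and the list had a camera adjusted p of 0.875. The KCNJ1 probe set was also below the lower quartile, at 3.31 in control and 3.00 in treated cells. ADAM10, ADAM17 and SOD2 had no probe set of their own and are not reported.

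Klotho has also been described as an inhibitor of insulin and IGF1 signalling. Of 31 measured components of that pathway, 23 were lower and 8 higher in treated cells, 0 passed the threshold over all probe sets or adjusted over the list alone, and the median difference was -0.07 (camera, adjusted p = 0.253); under the 3 other scalings 20 or 21 were lower, with a median of -0.02. RHEB, the small GTPase that activates mTOR, differed by 0.49 (95% interval 0.11 to 0.87) and the growth factor gene IGF1 by -0.25 (95% interval -0.46 to -0.03). Genes raised when growth factors are withdrawn, many of them targets of the FOXO factors that this pathway restrains, showed 17 higher and 19 lower among 36 measured members (camera, adjusted p = 0.878), with a median of -0.03 that lay above 0 under each of the 3 other scalings. YPEL2 differed by 0.57 and CDKN1B, the cell cycle inhibitor p27, by -0.24, and neither passed. The YPEL2 probe set was dim, at 3.08 in control and 3.65 in treated cells, below the lower quartile of all probe sets (4.70). The antioxidant list (23 genes, adjusted p = 0.965) held CAT, the hydrogen peroxide-degrading enzyme catalase, at 8.24 ± 0.26 in control and 8.17 ± 0.06 in treated cells (log2, SD, n = 3), and its members of smallest p were GPX1 (-0.22) and PRDX6 (0.17). The GPX1 difference was -0.08 without treated array 3, and that of PRDX6 0.09 without control array 1.

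Immediate-early genes, which answer growth factors within an hour, were 14 higher and 22 lower among 36 measured members as deposited, and 21 or 22 higher under the 3 other scalings, with 0 past the threshold over all probe sets or adjusted over the list alone and a camera adjusted p of 0.837. EGR3 (-0.36) and KLF4 (-0.24) had the smallest p. EGR1 measured 6.47 ± 0.10 in control and 6.43 ± 0.05 in treated cells (log2, SD, n = 3), FOS 6.04 ± 0.05 and 5.82 ± 0.13, and MYC 9.36 ± 0.06 and 9.37 ± 0.04. The interval of the MYC difference ran from -0.17 to 0.19. The output and feedback genes of ERK signalling (24 measured, adjusted p = 0.875) had EMP1 (-0.18) and ELK3 (-0.15) nearest to the threshold, and CCND1, the gene of cyclin D1, measured 9.21 ± 0.12 and 9.22 ± 0.08. All 24 ERK genes had intervals within a 1.5-fold change. The only time measured was 3.5 h, so these values do not show whether such genes had answered earlier and returned.

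**Figure D2:**
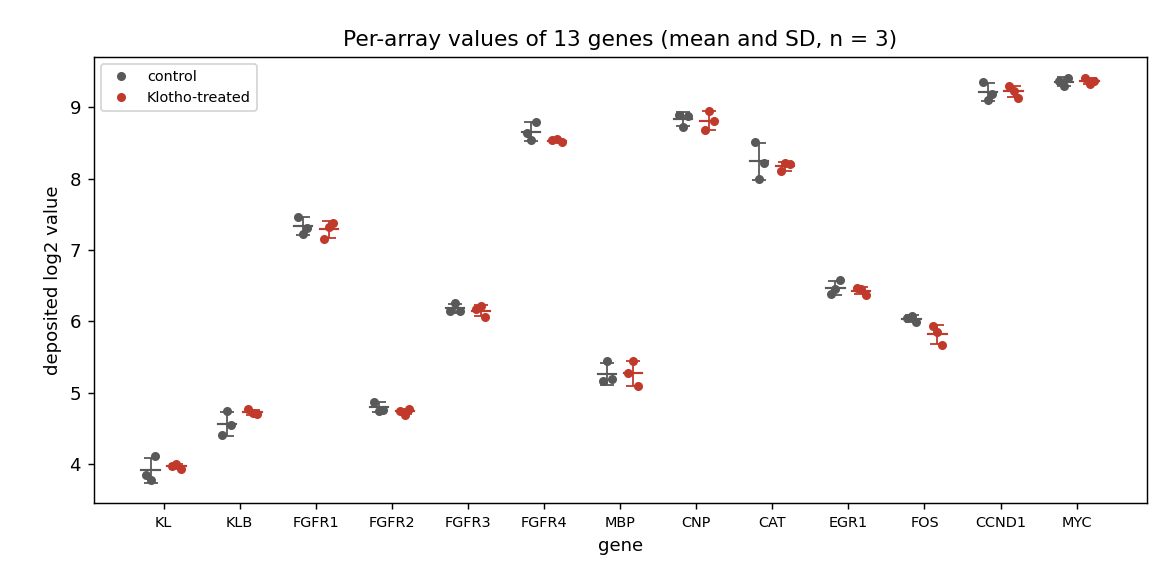
Deposited log2 values of 13 genes on the 3 control arrays (grey) and the 3 Klotho-treated arrays (red); points are single arrays, the horizontal bar is the mean and the error bar the SD. The groups overlap or lie within 0.22 of each other for every gene, and FOS has the largest difference of the 13, at -0.22.

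The lists of other signalling pathways did not pass either. The Wnt list (24 genes, adjusted p = 0.875; median -0.05 as deposited, and within 0.01 of 0 under the 3 other scalings) had SP5 (0.16) and NKD1 (-0.13) nearest to the threshold. The TGF-beta and BMP list (30 genes, adjusted p = 0.261; median -0.06 as deposited, and -0.02 to -0.01 under the 3 other scalings) had the ligand gene BMP4 (-0.32) and the collagen gene COL1A2 (-0.26). The Notch list (16 genes, adjusted p = 0.837) had NOTCH3 (-0.15) and MFNG (0.25), the YAP list (21 genes, adjusted p = 0.438) WWC1 (-0.11) and NUAK2 (-0.11), and the SRF list of cytoskeletal genes (21 genes, adjusted p = 0.343) the non-muscle myosin gene MYH9 (-0.27) and CNN2 (-0.17). MFNG read 4.28 on control array 1 and 4.74 and 4.85 on control arrays 2 and 3, against 4.80 to 4.93 on the treated arrays. Glucocorticoid response genes (19 genes, adjusted p = 0.875) and circadian clock genes (19 genes, adjusted p = 0.261) had ANGPTL4 (0.16) and ALPL (-0.13), and PER2 (-0.18) and BHLHE40 (-0.20). NF-kappaB targets (27 genes, adjusted p = 0.837) and interferon-stimulated genes (29 genes, adjusted p = 0.875) had IL6 (0.31) and CXCL2 (0.51), and XAF1 (-0.35) and HERC5 (-0.14). In none of these lists did a member pass the threshold over all probe sets or adjusted over the list alone.

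Myelin and mature oligodendrocyte genes were 16 higher and 5 lower in treated cells among 21 measured members (17 or 18 higher under the 3 other scalings), with a median of 0.05, or 0.06 to 0.10 under those scalings, and camera gave the list an adjusted p of 0.056 (adjusted p = 0.958 with an estimated correlation between genes). No member passed over all probe sets or adjusted over the list alone. ASPA, the enzyme that splits N-acetylaspartate, differed by 0.36 (95% interval 0.16 to 0.57) and BCAS1, a marker of newly formed oligodendrocytes, by -0.20. The ASPA probe set was dim, at 2.02 in control and 2.38 in treated cells, below the lower quartile of all probe sets (4.70). MBP, which encodes myelin basic protein, measured 5.26 ± 0.15 in control and 5.27 ± 0.18 in treated cells (log2, SD, n = 3), with a 95% interval of the difference of -0.30 to 0.31, and CNP, an early myelin enzyme, 8.83 ± 0.10 and 8.81 ± 0.13. Without Klotho-treated array 3 the list's adjusted p was 0.00119, without control array 3 it was 0.0458, and without control array 1 and treated array 3 together it was 0.0183. It was 0.506 without treated array 1, 0.45 without treated array 2, 0.242 without control array 1, 0.172 without control array 2, 0.216 with cyclic loess and 0.375 without the probe sets below the lower quartile. The range over the 15 alternatives that tested the lists was 0.00119 to 0.958, the upper end with an estimated correlation.

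Oligodendrocyte precursor and lineage genes (18 measured, camera adjusted p = 0.875) held the zinc finger gene ZNF536, with a difference of -0.50 and an adjusted p of 0.030 over the list alone, and ZNF488 (-0.21). ZNF536 did not pass over all probe sets (limma, adjusted p = 0.998). Markers of cell types other than the labelled one were also examined. Which of them this line itself expresses was not tested. Astrocyte markers (17 genes, adjusted p = 0.918) had GJA1 (-0.46) and GFAP (-0.11), neuron markers (17 genes, adjusted p = 0.918) ENO2 (-0.15) and NEFM (-0.15), and microglia and blood markers (12 genes, adjusted p = 0.878) CD14 (-0.12) and TYROBP (0.17). Skeletal muscle and rhabdomyosarcoma markers (23 genes, adjusted p = 0.412) had the muscle intermediate filament gene DES, at 8.58 ± 0.09 in control and 8.32 ± 0.06 in treated cells (log2, SD, n = 3), and NCAM1 (-0.16). The mean signal of the muscle list in control cells was 7.75, against 5.38 for the myelin list, so its genes are not used here as an outside control.

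The remaining lists concerned growth, metabolism and stress. Nucleolar ribosome biogenesis genes were 23 lower and 8 higher among 31 measured members (20 or 21 lower under the 3 other scalings), with a median of -0.07, or -0.03 to -0.02 under those scalings, and a camera adjusted p of 0.0526 (adjusted p = 0.958 with an estimated correlation). The list's adjusted p was 0.0433 without control array 2, but 0.506 without treated array 1, 0.242 without control array 1, 0.216 with cyclic loess and 0.375 without the probe sets below the lower quartile of mean signal, of which the NPM1 probe set is 1. It ranged from 0.0433 to 0.958 over the alternatives. NPM1 was the only member to pass adjusted over the list alone (adjusted p = 0.00272), and the RNA polymerase I subunit gene POLR1B differed by -0.20. All 28 measured KRAB zinc finger genes were lower in treated cells (median -0.14; camera adjusted p = 0.0526, and adjusted p = 0.958 with an estimated correlation), 0 of them passed the threshold, and ZNF180 (-0.38) and ZNF256 (-0.26) had the smallest p. ZNF180 read 6.9 on control array 1 and 6.2 on control arrays 2 and 3, against 6.0 to 6.2 on the treated arrays. The mean of the KRAB list spanned 0.53 between control array 1, the highest, and treated array 1, the lowest, and its SD among the 3 controls (0.22) was larger than the difference between the groups. The list mean went with the component of largest variance over all probe sets, described further below. Control array 1 and treated array 3 were highest on both, and treated array 1 was lowest on both. The list can therefore not be read as a signal separate from that component. With quantile normalization or median centring 23 of the 28 were lower (medians -0.08 and -0.09), and with cyclic loess 25 (median -0.08). The list's adjusted p ranged from 5.8e-05 to 0.958 over the alternatives: it was 5.8e-05 without treated array 3, 0.000337 without control array 3 and 0.0433 without control array 2, whereas without control array 1 the direction of the test turned to higher (adjusted p = 0.923). It was 0.641 without treated array 1, 0.405 without treated array 2 and 0.251 without the probe sets below the lower quartile. With median centring it was 0.00649, with cyclic loess 0.0526 and without control array 1 and treated array 3 together 0.0239. With the leading component of the deviations within groups as a covariate it was 0.000792. That covariate takes out spread within groups by its construction, which can itself lower p. All the low values of this list used camera's preset correlation of 0.01, whereas the correlation estimated for it was 0.65. A preset so far below the estimate makes p too small, so these values do not establish a shift of the list.

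The other lists had adjusted p values of 0.162 or more, and no member of them passed over all probe sets or adjusted over the list alone. Extracellular matrix genes (36 genes, 29 lower, adjusted p = 0.162) had FBN1 (-0.25) and COL1A2 (-0.26), fatty acid synthesis genes (20 genes, 17 lower, adjusted p = 0.213) FASN (-0.18) and FADS1 (-0.16), and DNA replication genes (37 genes, 32 lower, adjusted p = 0.219) CHAF1A (-0.30) and RPA2 (-0.21). Under the 3 other scalings 24 to 26, 14 and 22 to 25 members of these lists were lower, and without control array 2 the DNA replication list had an adjusted p of 0.0477 (range over alternatives 0.0477 to 0.958). With an estimated correlation over all 6 arrays the adjusted p of the DNA replication list was 0.958. G2/M genes (37 genes, adjusted p = 0.875) had PTTG1 (-0.30) and MKI67 (-0.25), and p53 targets and CDK inhibitors (30 genes, adjusted p = 0.875) CDKN1B (-0.24) and SPATA18 (0.15). Cholesterol synthesis and uptake genes (18 genes, adjusted p = 0.878) had TM7SF2 (-0.12) and PMVK (-0.12), and glycolysis and hypoxia genes (30 genes, adjusted p = 0.878) TPI1 (0.39) and HK1 (-0.15). The probe sets of TPI1 (3.02 in control, 3.41 in treated cells) and SPATA18 (3.86 and 4.02) were below the lower quartile of all probe sets (4.70). ATF4 targets (36 genes, adjusted p = 0.924) had CARS1 (-0.20) and SLC7A1 (-0.26), endoplasmic reticulum chaperones (24 genes, adjusted p = 0.805) SDF2L1 (-0.18) and HYOU1 (-0.12), and heat shock proteins (16 genes, adjusted p = 0.875) HSPD1 (-0.34) and HSPA2 (-0.19). Oxidative phosphorylation subunits (32 genes, adjusted p = 0.875) had COX4I1 (-0.24) and COX5A (0.19), cytosolic ribosomal proteins (25 genes, adjusted p = 0.261) RPL22 (0.18) and RPL35 (-0.64), and histones (21 genes, adjusted p = 0.439) H2BC21 (-0.24) and H2BC3 (0.19). RPL35 read 7.87 on control array 2 and 6.62 and 7.28 on control arrays 1 and 3. On the treated arrays it read 6.21 to 6.89. The histone list had an adjusted p of 0.0458 without control array 3 (range 0.0458 to 0.958), and the ribosomal protein list 0.0239 without control array 1 and treated array 3 (range 0.0239 to 0.99). With an estimated correlation over all 6 arrays the adjusted p was 0.958 for the histone list and 0.958 for the ribosomal protein list. Short-lived transcripts and splicing kinases (11 genes, adjusted p = 0.909) had SERTAD1 (0.18) and IER2 (-0.15).

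Over all 38 lists, camera called 0 at an adjusted p under 0.05 and 7 at an unadjusted p under 0.05. With an estimated correlation it called 0 at either level. The adjusted p of 0.958 given for several lists with that correlation is shared by most lists, so it does not tell them apart. Camera's unadjusted p with the estimated correlation was 0.185 for the myelin list, 0.277 for ribosome biogenesis and 0.476 for the KRAB list. Fry's directional test and its mixed test each called 0 after adjustment and 1 without. The medians of 34 lists were below 0, which moved with the scaling: 62.6% of all genes had a negative difference as deposited, 42.7% after centring each array on its median, and the medians of 22 lists changed sign under at least 1 of the 3 other scalings. Median centring moves the difference of every gene by the same amount, so a change of sign under it follows from the size of the median. Some of the 22 lists changed sign only there. Camera compares a list with all other genes, and for 9 lists it gave the direction as higher while the median was below 0. The 877 distinct measured genes of these lists included 816 whose interval lay within a 1.5-fold change, and NPM1 and ZNF536 were the only 2 to pass when adjusted over a list alone. That adjustment was made within each list and not across the 38 lists, so a few such passes can arise by chance.

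**Figure D3:**
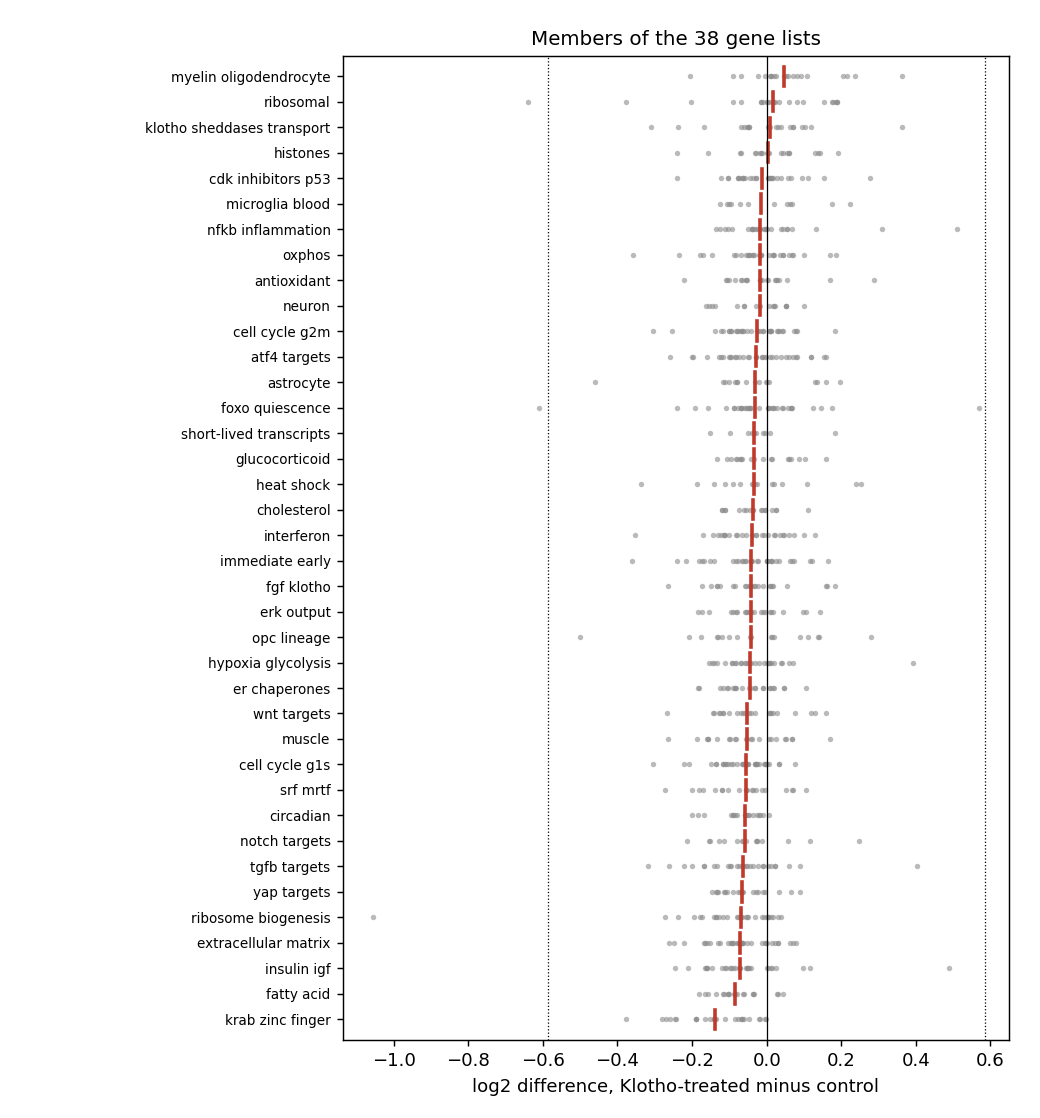
Log2 differences (x axis, treated minus control) of the measured members of the 38 gene lists; each grey point is a gene, each red bar a list's median, and the dotted lines mark a 1.5-fold change. Medians lie between -0.14 for the KRAB zinc finger genes and 0.05 for the myelin genes, and no list has an adjusted p under 0.05.

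**Figure D4:**
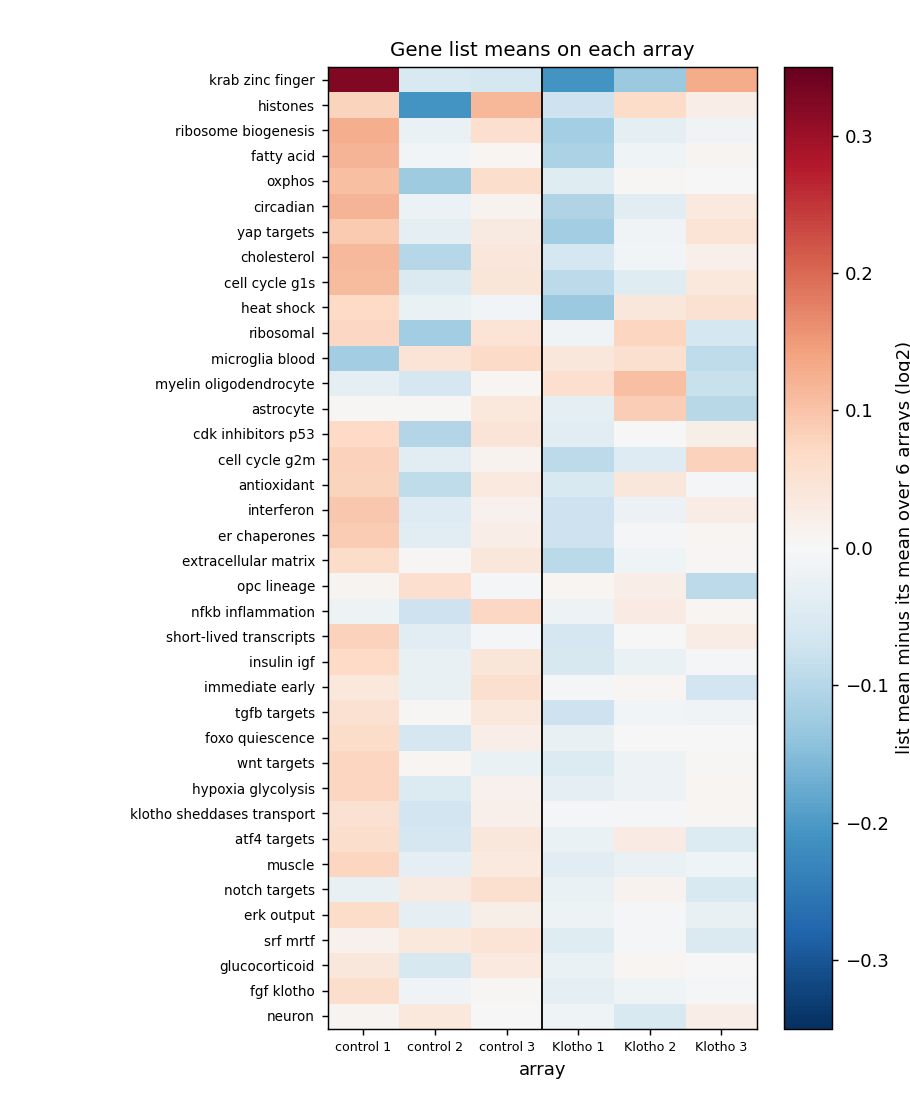
Mean log2 value of each gene list on each array (columns, 3 control and 3 Klotho-treated), as the deviation from the list's mean over the 6 arrays. The KRAB zinc finger list ranges over 0.53, from control array 1 to treated array 1, and the histone list over 0.33, between control arrays 2 and 3.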

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

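The alternatives without control array 1 and treated array 3, with an array component as a covariate and with only annotated probe sets were chosen after seeing the data; the others were planned. The count of probe sets past an adjusted p under 0.05 stayed at 0 under every alternative run, with the smallest adjusted p between 0.0932 (without control array 3) and 0.9997 (replicate block), and 0.0962 with array quality weights. The count at an unadjusted p under 0.05 (703) became 436 without probe sets below the lower quartile of mean signal and 228 without those below the median, where fewer were tested. It was 438 when only the 14232 representative probe sets were fitted, against 295 for the same ones in the fit of all. It was 530 when only the 16840 annotated probe sets were fitted, where the smallest limma adjusted p was 0.145. It was 1644 with array quality weights, 1127 without control array 1 and treated array 3, 1213 with the array component as a covariate, and 577 to 1200 when each array was left out, the lowest without treated array 2 and the highest without treated array 3; the cause was not tested. The count of shifted lists (0) was 1 with median centring, 2 with the replicate block, 0 to 3 when each array was left out, 3 without control array 1 and treated array 3, and 1 with the array component, and the cause was not tested. All these calls used camera's preset correlation. The count of shifted lists stayed at 0 with camera's estimated correlation and with fry's directional test. The KRAB zinc finger list (lower) was among those called in each setting that called any, the myelin list (higher) without control array 3 (with the histones), without treated array 3 and without control array 1 and treated array 3 (with the ribosomal proteins), ribosome biogenesis (lower) with the block (adjusted p = 0.0478, as for the KRAB list) and without control array 2, and DNA replication (lower) without control array 2. No list was called without control array 1, treated array 1 or treated array 2. Same-numbered arrays did not deviate together from their group means (r = -0.18, 0.06 and -0.14 across probe sets for numbers 1, 2 and 3), so they were not taken as pairs, and the replicate block left 662 probe sets at an unadjusted p under 0.05. Of 95 named genes, 0 passed under any of 13 alternatives and 0 with an unadjusted p under 0.05 changed sign, while 9 others did in 33 of 1235 values: KL, FGFR1, FGFR3, MBP, CNP, CAT, EGR1, CCND1 and MYC.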

Other observations

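The means of several gene lists differed between arrays of the same group. KRAB zinc finger genes, a large family of repressors of transposable elements, had a list mean 0.32 above the mean of the 6 arrays on control array 1 and 0.13 above it on treated array 3, and 0.21 and 0.13 below it on treated arrays 1 and 2. In the same order, these arrays scored 32.8, 18.4, -26.3 and -14.9 on the component of largest variance described below. Histone genes were 0.21 below their mean on control array 2 and 0.12 above it on control array 3. Oxidative phosphorylation genes were 0.10 above their mean on control array 1 and 0.12 below it on control array 2. Ribosome biogenesis, fatty acid synthesis and circadian clock genes had their highest mean on control array 1 and their lowest on treated array 1, with ranges over the arrays of 0.25, 0.23 and 0.22. The upper quartile of all probe sets was also highest on control array 1 (8.19) and lowest on treated array 1 (7.94). The ranges of these lists were not separated from that difference between whole arrays, which many other lists shared. Myelin genes were 0.11 above their mean on treated array 2 and 0.08 below it on treated array 3.

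All tests of explanations in this part were chosen after the result was seen, except the counts of other splits and the tests of quantile normalization and of dim probe sets, which were written before their values were known. The fit with array quality weights and the limma and camera tests had been planned, but not as tests of these explanations. The main result is an absence of calls. Whether the spread was too large to call 2-fold changes was not decided. For 98.7% of the genes, those with dim probe sets included, the interval lay inside a 2-fold change, which bounds each gene's difference in signal taken alone. The intervals are not adjusted over all probe sets, so they do not show that a 2-fold change would have passed. Of the 4 genes that differed by more than 2-fold, 0 passed. The 6 arrays can be split 3 against 3 in only 10 ways, too few for a share under 0.05, and a real count of 0 is met by every split whatever their number: 10 of 10 for probe sets past the adjusted threshold (highest other 1) and 10 of 10 for gene lists (highest other 4). Unequal array quality stays open as a candidate explanation: with array quality weights 1644 probe sets had an unadjusted p under 0.05, above the 1101 of chance, yet 0 passed after adjustment. The weights were 2.77 for treated array 2 and 1.97 for control array 3, against 0.55 to 0.82 for the other arrays. They were estimated from these same 6 arrays, which can itself raise an unadjusted count.

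A component on which an array of each group scored high may lower the number of small p-values: it carried 33.8% of the variance, with scores of 32.8 for control array 1 and 18.4 for treated array 3 against -26.3 to -3.05 for the other 4, and 179 of the 200 probe sets with the largest loadings (89.5%) were unnamed, against 23.5% of all probe sets. The 4 splits that set these 2 arrays together, with control array 3, control array 2, treated array 2 or treated array 1, gave 2565, 1829, 1254 and 728 probe sets at an unadjusted p under 0.05, against 703 for the real split; the highest points to a structure of the samples, but the splits are not independent of the component and the lowest is near the real count. Unequal array distributions are argued against, since 114.1% of the excess of unnamed over named probe sets on these arrays (0.06 on the log2 scale) was left after quantile normalization. A response to Klotho was not decided, since the overlap of the groups' scores (2-sided exact permutation p = 0.50, where 0.10 is the smallest possible) follows from picking a pattern with an array of each group. Signal from DNA or unspliced RNA remains a candidate explanation that cannot be told apart from others: named probe sets below the lower quartile of mean signal lay lower on these arrays (-0.0556 on the log2 scale for the lower of them against the highest of the other 4), but normalization had left the arrays' lower quartiles within 0.0374 of each other and can itself force this, and what the unnamed probe sets target is not stated in the tables used here.

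The labels name serum-free medium for the treated cells only, so that removal of serum and Klotho could both separate the groups. If serum removal had moved serum-responsive genes by 1.5-fold or more on average (0.585 on the log2 scale), the immediate-early list would be lower and the cholesterol and growth factor withdrawal lists higher by at least that much. The largest difference between any treated and any control array in the mean of these 3 lists was 0.174. A mean shift of that size was therefore not seen in these 3 lists. The size was set after the result was seen, so this bears on large shifts only. It does not decide whether serum removal separates the groups. Smaller shifts were not called either: camera gave the 3 lists adjusted p values of 0.837, 0.878 and 0.878, and limma called 0 of their genes, with 2, 0 and 3 at an unadjusted p under 0.05, which does not show that there was none. Whether the controls were also kept without serum is not stated in the labels.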
